A study of Mus musculus with 117 samples.

How the data were processed

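RNA was measured in exocrine glands of female mice of 2 immunodeficient strains, NOD.CB17-Prkdc scid/J (NOD-scid) and B6.CB17-Prkdc scid/SzJ (B6-scid), both without mature T and B cells. Pancreas came from mice of 6 weeks (5 per strain), submandibular gland from mice of 9 and of 15 weeks (5 per strain and age), and lacrimal gland from mice of 15 weeks (5 B6-scid, 4 NOD-scid). Each of the 39 gland samples was hybridised to 3 Affymetrix MG-U74 version 2 array designs, A, B and C, which made 117 arrays. Per the labels, the glands were homogenised in Trizol, and biotin-labelled cRNA was made from 10 microg of total RNA. How the mice were killed and how the glands were dissected is not given in the sources used here.

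The deposited values were linear signal intensities from MAS5, per the submitters' processing notes. No detection calls were used here. The 2% trimmed mean of the deposited intensities lay between 2500.5 and 2501.7 on each of the 117 arrays, so the arrays had been scaled to 1 level before deposit. Median deposited signals were 1030.6 to 1213.6 on design A, 1344.6 to 1653.6 on design B and 979.6 to 1379.4 on design C. Each probe set was read once per gland sample, so the number of mice per group limits the precision.

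The intensities were rescaled to a 2% trimmed mean of 500 per array, and values named in the results are on that scale, as arithmetic mean ± SD over mice. Between 65.3% and 70.8% of probe sets reached a scaled signal of 100 on design A, 73.5% to 77.8% on design B and 65.5% to 74.1% on design C. The designs held 12488, 12477 and 11934 probe sets, 36899 together, of which 66 on each design were controls and were left out. Gene names came from the platform's annotation, updated through a RefSeq gene table of assembly GRCm38.p6. That table served for names and for which genes neighbour each other, and no coordinates are given because the files name no genome build. Of the probe sets, 29197 had 1 gene symbol, 724 had several and 6846 had none, and 29110 matched the RefSeq table. No gene was named from a probe set with several symbols.

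Signals were tested as log2(signal + 32) with lmFit and eBayes of limma 3.58.1 in R 4.3.3. A fold change on that scale understates the change of genes with low signals. Probe sets entered a test when their scaled signal was at least 100 on at least 4 of the arrays in the fit. P-values were adjusted over all 3 designs with the Benjamini-Hochberg method, and probe sets with an adjusted p under 0.05 were called. The 4 strain comparisons (NOD-scid minus B6-scid) were pancreas, submandibular gland at 9 weeks, submandibular gland at 15 weeks and lacrimal gland. Within the submandibular gland, each strain was also compared between ages (15 minus 9 weeks), and the strain difference was compared between ages. The submandibular comparisons shared 1 fit of 20 samples. The strain difference was compared between lacrimal and submandibular gland over the 19 samples of 15 weeks.

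Gene lists were tested with camera of limma at its preset correlation of 0.01, on 1 probe set per gene (design A before B before C, the highest mean within a design), where at least 5 genes of a list were tested. The preset correlation gives small p-values for lists whose members vary together, so each list was tested again with a correlation estimated from the data. The 32 lists were written from general knowledge of gene function. They were acinar digestive enzymes, the Reg family, pancreatic islet, duct epithelium, salivary kallikreins and growth factors, salivary secretory proteins, lacrimal secretory proteins, Harderian gland and sebaceous, sublingual gland, MHC class II, MHC class I and antigen processing, interferon response, macrophage, dendritic cell, NK cell, T cell, B cell and immunoglobulin, neutrophil, lymph node stroma, chemokines and cytokines, complement, ER stress and protein folding, oxidative stress, oxidative phosphorylation, ribosomal proteins, extracellular matrix, endothelium, adipocyte, skeletal muscle, proliferation, apoptosis, and Idd candidate genes (genes in mapped intervals for diabetes or exocrine disease of NOD mice). A count over a list is given both over all probe sets tested and adjusted over the list alone.

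Named genes followed a rule. For each strain comparison these were the 10 largest increases and the 10 largest decreases among called probe sets with 1 gene symbol and no overlap between the strains, 1 probe set per gene. For the age comparisons and both differences between comparisons these were the 5 largest each way. Up to 4 members with the smallest p were added from each list that camera called or of which at least a share of 0.25 was called, and Prkdc, Nnt, Hc, Ins2, Bpifa2, Egf, Klk1 and Aqp5 were always followed. Of the strain differences shared by all 4 comparisons, the 10 whose smallest fold change was largest were named. A few further transcripts were chosen after their values were seen, and the text says so there.

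The design, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 8 and 128, no filter on low signals, a minimum signal of 200, median scaling, quantile normalization, the deposited scale, 1 fit of all 39 samples, the replicate number as a block, eBayes with trend and robust settings, adjustment within each design, and the log2 ratio of the 3' to the 5' Gapdh control probe sets of the same array as a covariate for RNA quality. Each replicate was also left out in turn, and the lists were tested with an estimated correlation and with the probe set of highest mean over all designs. Ranges of an adjusted p over alternatives leave out the fits with a replicate block. Alternatives chosen after seeing the data left out the 9-week samples numbered 4 and 5, left out both B6-scid lacrimal samples high in salivary transcripts, or used the replicate number within age as a block.

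The fits were tested on simulated data, in which 200 probe sets of each design were shifted by a log2 change of 1 or 2. For a change of 1, 38.3% were recovered in the pancreas fit, 33.2% and 31.7% in the submandibular fits of 9 and 15 weeks and 25.9% in the lacrimal fit. For a change of 2 these shares were 78.9%, 82.3%, 82.8% and 76.3%. In the age fits 33.0% (B6-scid) and 32.9% (NOD-scid) were recovered at a change of 1, against 12.1% in the strain-by-age fit and 14.9% in the strain-by-gland fit. False calls made up 3.64% of the simulated calls in pancreas, 11.9% and 4.70% in submandibular gland at 9 and 15 weeks, 7.27% in lacrimal gland, 5.80% and 4.35% for age in B6-scid and NOD-scid, 3.50% for strain by age and 9.09% for strain by gland. A shifted list ranked 1 of 31 in the pancreas simulation, with 0 other lists called. The simulated noise was independent between probe sets, so this run could not show false calls of lists whose members vary together. For each fitted comparison, 100 splits of the samples were counted, the real one included. Other software was statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and scipy 1.17.1.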

Results

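Exocrine glands of NOD-scid mice were compared with those of B6-scid mice. The question was which transcripts differ, without T and B cells, between a strain prone to autoimmune disease of pancreas and exocrine glands and a strain that is not. RNA levels were measured in pancreas at 6 weeks of age (5 mice per strain), submandibular gland at 9 and at 15 weeks (5 mice per strain and age) and lacrimal gland at 15 weeks (5 B6-scid and 4 NOD-scid mice). Each of the 39 gland samples was read on 3 array designs, 117 arrays in all. The designs hold different probe sets, so the number of mice per group limits the precision. Ranges of an adjusted p over alternatives leave out the replicate block. Levels are scaled signals, as mean ± SD over the mice of a group, and differences are log2 fold changes of signal + 32 with their standard error. On design A, a sample's mean correlation with the others of its group averaged between 0.908 and 0.949 by group. On design C it averaged 0.756 and 0.752 in the B6-scid and NOD-scid submandibular samples of 9 weeks, against 0.848 and 0.842 in those of 15 weeks. On design A the 3' to 5' signal ratio of Gapdh lay between 0.664 and 1.27 and that of Actb between 1.30 and 4.34. The mean Actb ratio was 2.45 ± 1.16 in the B6-scid submandibular samples of 9 weeks and 1.68 ± 0.213 in those of 15 weeks. In the NOD-scid submandibular samples it was 2.17 ± 0.405 and 1.70 ± 0.151. Between B6-scid and NOD-scid it was 2.54 ± 0.467 and 2.04 ± 0.0421 in pancreas, and 1.82 ± 0.375 and 1.85 ± 0.149 in lacrimal gland.

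In pancreas, Ctrc, B4galnt1, Pigr and Reg3g were among the genes that differed between the strains. Ctrc, which encodes the digestive protease chymotrypsin C, was higher in NOD-scid pancreas by 4.52 (SE 0.17, adjusted p = 2.3e-07), at 257310 ± 30364 against 11219 ± 1446 in B6-scid (n = 5 each). B4galnt1, an enzyme of ganglioside synthesis, was lower by -3.91 (SE 0.14, adjusted p = 2.3e-07), at 33.5 ± 7.09 against 955 ± 120. Pigr, the receptor that carries polymeric immunoglobulin across epithelia, was lower by -2.34 (SE 0.18), at 2635 ± 512 against 13378 ± 2274. The antimicrobial lectin Reg3g was lower by -2.68 (SE 0.25), at 7021 ± 2888 against 42600 ± 5553. Ly6e, a membrane-anchored protein of the Ly6 family, was lower by -4.55 (SE 0.21), with 1 of its 2 other probe sets also called lower (-1.50). The adhesion protein Vtn was higher by 2.51 (SE 0.20), at 9677 ± 2252 against 1663 ± 343. Mtm1 was higher by 3.14 on 1 probe set, while 0 of its 3 other probe sets were called. In all, 186 of 28733 probe sets were called, 68 higher and 118 lower in NOD-scid, and 149 of them differed at least 2-fold. The count was 112 without B6-scid replicate 3, 122 without B6-scid replicate 5 and 119 without NOD-scid replicate 2.

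Among the fixed lists in pancreas, 6 lay lower in NOD-scid at the preset correlation, 0 with an estimated correlation and 0 after quantile normalization. The Reg family (7 genes tested, adjusted p = 0.0187) had 1 gene called lower, Reg3g, also 1 adjusted over the list alone. Reg1 (-0.19), Reg2 (-0.29) and Reg3b (-0.24) did not pass. Its adjusted p was 0.482 with an estimated correlation (0.0111 to 0.482 over its alternatives), 0.0533 and 0.0709 without B6-scid replicates 3 and 4, and 0.0550 without NOD-scid replicate 2. Of 29 genes for ER stress and protein folding (adjusted p = 0.0187), the chaperone-pathway genes Creld2 (-0.76, adjusted p = 0.0381) and Manf (-0.79, adjusted p = 0.0431) were called lower. Adjusted over the list alone there were 5, and 27 genes did not pass. That list's adjusted p was 0.482 with an estimated correlation (0.00638 to 0.482 over its alternatives), 0.0909 without B6-scid replicate 3, and 0.0550 and 0.103 without NOD-scid replicates 2 and 3. The calls of Creld2 and Manf each ended without each of 9 of the 10 libraries, reaching 0.0884 without B6-scid replicate 5 for Creld2 and 0.102 without NOD-scid replicate 2 for Manf (0.00791 to 0.0884 and 0.00499 to 0.102 over their alternatives). Of 31 ribosomal protein genes (adjusted p = 0.00748), 1 was called lower, Rps28 (-1.15, SE 0.14, 33942 ± 5371 against 74811 ± 6297), 2 adjusted over the list alone. The 2 other Rps28 probe sets did not pass (-0.27 and 0.11). The ribosomal list had an adjusted p = 0.482 with an estimated correlation (0.00254 to 0.482 over its alternatives).

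The MHC class II genes of the pancreas (12 tested, adjusted p = 0.0309) had 0 genes called and 0 adjusted over the list alone, with H2-Aa at -1.20 (adjusted p = 0.247). The class II list had an adjusted p = 0.303 with an estimated correlation (0.0172 to 0.303 over its alternatives), 0.0709 without B6-scid replicate 3 and 0.0555 without NOD-scid replicate 1. The interferon response genes (28 tested, adjusted p = 0.0471) had 0 called and 3 lower adjusted over the list alone, with Irf9 at -0.80 and Rsad2 at -0.92, both at an adjusted p of 0.168. The interferon list had an adjusted p = 0.303 with an estimated correlation (0.0238 to 0.303 over its alternatives). It lay between 0.0533 and 0.168 without each of B6-scid replicates 1 to 5 and NOD-scid replicates 1, 3 and 5 in turn, the highest without B6-scid replicate 1. The salivary kallikreins and growth factors (13 tested, adjusted p = 0.00562) had 0 called and 1 lower adjusted over the list alone, and an adjusted p = 0.370 with an estimated correlation (9.0e-04 to 0.370 over their alternatives). Of 22 acinar digestive enzymes, Ctrc alone was called and 21 did not pass. The list's mean of 0.21 and its median of -0.13 differed in sign, with a camera test in the downward direction (adjusted p = 0.849). The islet list (22 genes, adjusted p = 0.658) had 1 gene called higher and 1 lower, 2 and 2 adjusted over the list alone. Ins2, an insulin gene, did not pass (0.42, SE 0.16, adjusted p = 0.375, 57703 ± 7752 against 43356 ± 6939).

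In submandibular gland at 9 weeks, Mucl1, Fbp1 and St6galnac1 were among the largest strain differences. Mucl1, a mucin-like secreted protein, was higher in NOD-scid by 7.12 (SE 0.35, adjusted p = 7.2e-11), at 140940 ± 26281 against 1072 ± 580 (n = 5 each). The gluconeogenic enzyme Fbp1 was higher by 4.52 (SE 0.21), at 1311 ± 335 against 25.5 ± 8.97. St6galnac1, which adds sialic acid to mucin-type sugars, was higher by 4.03 (SE 0.24), and the peptide-amidating enzyme Pam by 3.74 (SE 0.33). Apobec3, which restricts retroviruses, was lower by -3.49 (SE 0.35), at 47.3 ± 18.2 against 896 ± 372. The urate oxidase Uox was lower by -3.14 (SE 0.35) and the arginase Arg1 by -2.69 (SE 0.35), at 81.3 ± 49.6 against 669 ± 166. Nnt, a mitochondrial transhydrogenase with a known deletion in C57BL/6J mice, was higher by 1.48 (SE 0.21, adjusted p = 5.6e-04). Cxcl1, a chemokine for neutrophils, was lower by -2.64 (SE 0.53, adjusted p = 0.0136), and the clock-controlled gene Dbp by -2.77 (SE 0.52, adjusted p = 0.00864). Both reached 0.0931 without the 9-week samples numbered 4 and 5, a choice made after seeing the data (8.5e-04 to 0.0931 for Cxcl1 and 8.6e-04 to 0.0931 for Dbp over their alternatives). Of 32136 probe sets, 359 were called, 158 higher and 201 lower, 288 of them at least 2-fold, and leaving out each library gave 245 to 360.

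The kallikreins and growth factors, secreted by granular duct cells, lay higher in NOD-scid at 9 weeks (14 tested, adjusted p = 8.9e-04), with 1 called, Klk1b11 (1.80, SE 0.42, adjusted p = 0.0372), 6 adjusted over the list alone, and Egf at 1.38 (adjusted p = 0.108). The list had an adjusted p = 0.434 with an estimated correlation (4.1e-05 to 0.434 over its alternatives). Klk1b11 lost its call without each of 9 libraries, reaching 0.102 without B6-scid replicate 1 of 9 weeks (0.00959 to 0.102 over its alternatives). These kallikreins are near-identical paralogs whose probes may share targets, so the level of 1 member is uncertain. Klk1 was also abundant in pancreas (108510 ± 10214 in B6-scid and 88181 ± 11461 in NOD-scid). Acinar digestive enzymes also lay higher (20 tested, adjusted p = 0.00101), with 0 called and 4 adjusted over the list alone. Examples were Ctrc at 2.46 (adjusted p = 0.105) and Cpa1 at 2.09 (adjusted p = 0.193). The enzyme list had an adjusted p = 0.458 with an estimated correlation (1.7e-05 to 0.458 over its alternatives). It had 0.353 without NOD-scid replicate 1 of 9 weeks, in which Cela1 reached 19646 against 1563 to 2227 in the other 4. Genes of oxidative phosphorylation lay lower (52 tested, adjusted p = 0.00113), with 3 called, Cox6a1 (-1.02, SE 0.15, adjusted p = 7.8e-04), Atp5j (-0.77) and Ndufb5 (-0.68). Adjusted over the list alone there were 4, and 49 did not pass. The other Cox6a1 probe set did not pass (-0.35). Oxidative phosphorylation had an adjusted p = 0.434 with an estimated correlation (1.0e-04 to 0.434 over its alternatives) and 0.0824 without NOD-scid replicate 2 of 9 weeks. Atp5j lost its call without each of 5 libraries and Ndufb5 without each of 9, reaching 0.0634 and 0.0964 without that one. Ndufb5 also reached 0.111 after quantile normalization and 0.150 without the 9-week samples numbered 4 and 5. Salivary secretory proteins had 2 genes called higher and 3 lower of 21 (4 and 5 adjusted over the list alone). Their mean of 0.03 and median of 0.16 differed in sign from the downward camera test (adjusted p = 0.943).

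At 15 weeks, the submandibular glands of NOD-scid mice again had higher Mucl1 (6.49, SE 0.35, adjusted p = 4.2e-10, 53669 ± 3854 against 669 ± 459, n = 5 each), Fbp1 (4.20, SE 0.21) and St6galnac1 (4.35, SE 0.24, 1470 ± 423 against 42.5 ± 25.1). Gcnt1, which branches mucin-type sugars, was higher by 2.40 (SE 0.24, adjusted p = 6.0e-06), at 1599 ± 434 against 273 ± 55.7. Pigv, an enzyme of membrane anchor synthesis, was lower by -3.60 (adjusted p = 4.7e-05), Uox by -2.64 and Arg1 by -2.61 (SE 0.35), at 127.8 ± 61.7 against 892 ± 302. Nnt was higher by 1.25 (SE 0.21, adjusted p = 0.00332). In all, 191 probe sets were called, 72 higher and 119 lower, 168 of them at least 2-fold, and leaving out each library gave 147 to 207.

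The interferon response and MHC class II lists lay lower in NOD-scid submandibular gland at 15 weeks. Of 31 interferon response genes (adjusted p = 1.8e-05), 1 was called lower, the RNA sensor Ifih1 (-0.84, SE 0.18, 506 ± 33.9 against 938 ± 164). Adjusted over the list alone there were 2, and 30 did not pass. The other Ifih1 probe set lay on the opposite side (0.48, adjusted p = 0.999). Of 12 MHC class II genes (adjusted p = 0.00154), 2 were called lower, 6 adjusted over the list alone. These were Cd74, the chain that escorts class II molecules (-1.004, SE 0.22, 1730 ± 245 against 3489 ± 371), and the protease Ctss (-1.01, SE 0.21, 855 ± 79.0 against 1798 ± 478). Each of the 3 calls ended without each of 7 or 8 of the 20 libraries in the fit. They reached 0.0879 without B6-scid replicate 4 for Ifih1, 0.101 without B6-scid replicate 2 for Ctss and 0.105 without NOD-scid replicate 1 for Cd74, all of 15 weeks. Ifih1 also reached 0.392 in 1 fit of all 39 samples (0.00704 to 0.392 over its alternatives). The adipocyte list lay higher (11 tested, adjusted p = 0.00676), with 1 called, the lipase Lpl (1.22, SE 0.19, adjusted p = 0.00168, 497 ± 84.7 against 197 ± 44.6), also 1 adjusted over the list alone. These interferon, class II and adipocyte lists each had an adjusted p = 0.0454 with an estimated correlation, the highest of their 29 alternatives, whose lowest values were 4.0e-06, 4.1e-04 and 0.00253.

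Kallikreins and growth factors lay higher at 15 weeks as well (14 tested, adjusted p = 4.0e-04), with 0 called on the probe sets used for the list and 4 adjusted over the list alone. The other probe set of Klk1b8 was called higher (3.17, adjusted p = 0.0309). The list had an adjusted p = 0.330 with an estimated correlation (2.1e-05 to 0.330 over its alternatives). Acinar digestive enzymes (20 tested, adjusted p = 0.00676) had 0 called and 0 adjusted over the list alone, with an adjusted p = 0.720 with an estimated correlation (3.5e-04 to 0.720 over their alternatives). They reached 0.0991 without NOD-scid replicate 1 of 15 weeks, in which Cela1 reached 1146 against 95.7 to 159 in the other 4. Extracellular matrix genes (38 tested, adjusted p = 0.0195) had 0 called and 1 higher adjusted over the list alone, with Col3a1 at 1.17 (adjusted p = 0.0839). The matrix list had an adjusted p of 0.244 with an estimated correlation (0.00768 to 0.244 over its alternatives), 0.0725 without B6-scid replicate 3 and 0.0566 without NOD-scid replicate 4 of 15 weeks.

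In lacrimal gland, the folding genes Hspa5 and Creld2 were higher in NOD-scid mice, and B2m and the chemokine gene Cxcl1 were lower. Hspa5, the main chaperone of the endoplasmic reticulum, was higher by 1.24 (SE 0.16, adjusted p = 0.00731), at 19566 ± 2531 (n = 4) against 8263 ± 806 (n = 5), and Creld2 by 1.74 (SE 0.25), at 2400.0 ± 646 against 697 ± 187. B2m, the light chain of class I molecules, was lower by -2.21 (SE 0.31, adjusted p = 0.00985), at 1303 ± 241 against 6602 ± 3302, and Cxcl1 by -3.30 (SE 0.32, adjusted p = 0.00114), at 29.1 ± 15.6 against 596 ± 260. Ly6e was lower by -7.10 (SE 0.40, adjusted p = 4.1e-05). Fxyd3, a regulator of the sodium pump, was lower by -2.85 (SE 0.17), at 887 ± 149 against 6574 ± 772. Noct was lower by -2.82 (SE 0.22), though its other probe set lay on the opposite side without passing (0.49, adjusted p = 0.345). The endothelial receptor Notch4 was higher by 4.70 (SE 0.41), at 5895 ± 1396 against 221 ± 120, on 1 probe set, while its 2 others did not pass (-0.18 and 0.25). Pam was higher by 3.59 (SE 0.30), and BC018473 by 6.43 (SE 0.39), at 18466 ± 3347 against 204 ± 114. In all, 330 of 27686 probe sets were called, 145 higher and 185 lower, 298 of them at least 2-fold. The count was 206 and 202 without B6-scid replicates 3 and 4, and 201, 168, 148 and 202 without NOD-scid replicates 1, 2, 3 and 4.

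Of 31 genes for ER stress and protein folding in lacrimal gland (adjusted p = 7.5e-07), 6 were called higher, among them Hspa5, Creld2, Sdf2l1 (1.47, SE 0.22, 5353 ± 1311 against 1875 ± 183) and Pdia4 (1.70, SE 0.29). Adjusted over the list alone there were 16 higher and 1 lower. That list had an adjusted p = 0.145 with an estimated correlation (1.9e-07 to 0.145 over its alternatives). Pdia4 lost its call without each of 5 libraries, reaching 0.0777 without NOD-scid replicate 3, and 0.115 with the RNA quality covariate (0.00432 to 0.115 over its alternatives). Without both B6-scid samples high in salivary transcripts Sdf2l1 reached 0.0751 (1.7e-04 to 0.0751 over its alternatives). Of 16 genes of class I presentation (adjusted p = 7.9e-04), 1 was called lower, B2m, against 6 adjusted over the list alone. H2-D1 did not pass on the probe set used for the list (-1.22, adjusted p = 0.0595) but was called lower on 1 of its 2 others (-1.94, adjusted p = 0.0163), and Psmb8 did not pass (-1.18, adjusted p = 0.0787). Its adjusted p was 0.127 with an estimated correlation (2.4e-04 to 0.127 over its alternatives). B2m reached 0.0602 with the RNA quality covariate (8.7e-07 to 0.0602 over its alternatives). Of 29 interferon response genes (adjusted p = 4.2e-06), 1 was called lower, Ifi204 (-2.003, adjusted p = 0.0201), against 2 adjusted over the list alone. The interferon list had an adjusted p = 0.404 with an estimated correlation (2.4e-08 to 0.404 over its alternatives). The other Ifi204 probe set lay on the opposite side (0.40, adjusted p = 0.715). Ifi204 reached 0.0634 without NOD-scid replicate 3 and 0.107 without both B6-scid samples high in salivary transcripts, a choice made after seeing the data (6.3e-06 to 0.107 over its alternatives).

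Macrophage genes lay lower in NOD-scid lacrimal gland (20 tested, adjusted p = 0.0162), with 1 called, the signalling adapter Tyrobp (-1.36, SE 0.18, adjusted p = 0.00747, 141 ± 33.7 against 407 ± 47.9), against 5 lower and 1 higher adjusted over the list alone. The macrophage list had an adjusted p of 0.404 with an estimated correlation (7.0e-04 to 0.404 over its alternatives), 0.0526 and 0.0560 without B6-scid replicates 1 and 4 and 0.0552 without NOD-scid replicate 4. Idd candidate genes lay lower (18 tested, adjusted p = 0.0370), with 1 called and 3 adjusted over the list alone. The Idd list had an adjusted p = 0.404 with an estimated correlation (0.0111 to 0.404 over its alternatives), 0.0631 without B6-scid replicate 4, and 0.0504 and 0.179 without NOD-scid replicates 3 and 4. With no filter on low values it had 0.174, and its median went from -0.37 to 0.01. Kallikreins and growth factors lay lower (12 tested, adjusted p = 7.3e-04), with 0 called and 5 adjusted over the list alone. This list had an adjusted p = 0.511 with an estimated correlation (6.1e-07 to 0.511 over its alternatives). Klk1 itself did not pass (-3.01, SE 0.86, adjusted p = 0.152, 1218 ± 1844 against 7030 ± 7594). Salivary secretory transcripts were very unequal among the B6-scid mice: Amy1, the salivary amylase, read 185010 and 181640 in replicates 2 and 3 and 37.0 to 111 in the other 3. In the same 5 mice Bpifa2, a saliva protein of parotid gland, read 160310 and 268250 against 348 to 395. All 5 lay above the 4 NOD-scid mice (70.3 to 75.8), though the strain difference did not pass with this spread (-5.55, SE 2.09, adjusted p = 0.277). The salivary list had 2 genes called higher in NOD-scid of 19 (4 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.408). The lacrimal secretory list had 2 higher and 1 lower of 20 (4 and 8 adjusted over the list alone, camera adjusted p = 0.505).

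**Figure D1:**
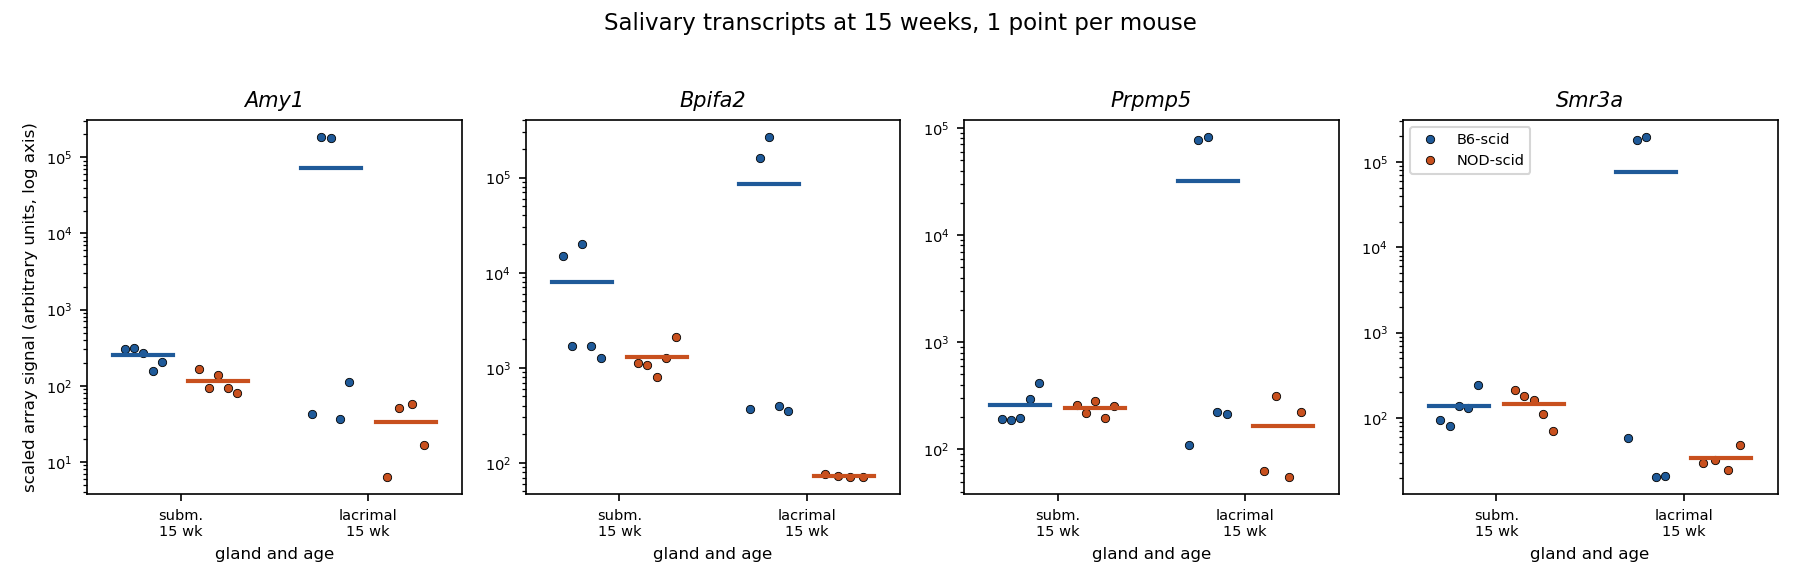
Scaled signal (log axis, arbitrary units) of Amy1, Bpifa2, Prpmp5 and Smr3a in submandibular (subm.) and lacrimal gland at 15 weeks, with 1 point per mouse, B6-scid in blue and NOD-scid in orange, and a line at the arithmetic mean of each group. B6-scid lacrimal replicates 2 and 3 lie far above the other lacrimal samples in all 4 transcripts, with Smr3a at 179940 and 195550 against 20.2 to 59.1 in the other B6-scid mice.

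Across the 4 strain comparisons, 22 of 25450 probe sets, of 18 genes, were called in the same direction in each, 4 higher and 18 lower in NOD-scid, where independent lists would share 2.4e-05. Ly6e differed by -4.55 in pancreas, -3.25 and -2.23 in submandibular gland at 9 and 15 weeks and -7.10 in lacrimal gland, and Rpgrip1, a protein of photoreceptor cilia, by -3.51, -3.94, -3.37 and -3.18, while 0 of the other Rpgrip1 probe sets tested in submandibular or lacrimal gland were called. Fbp1 was higher by 2.08, 4.52, 4.20 and 3.47, and Gfer by 0.81, 1.54, 1.12 and 1.39. Gramd3, Tmem14c, AI506816, Spg21, Snhg6, D17H6S56E-5 and the lysosomal protease Ctsc were lower in all 4, with Ctsc at -2.03, -1.85, -1.76 and -2.49. The other AI506816 probe set was called higher in submandibular gland at 9 weeks (2.39) and 15 weeks (2.04) and in lacrimal gland (2.47). Ctsc had a further probe set on the opposite side in all 4 without passing (0.49 to 0.68). Another Ctsc probe set was called lower in submandibular gland at 15 weeks (-2.80) and lacrimal gland (-3.88). Tmem14c in pancreas lost its call without each of 7 libraries, reaching 0.0850 without B6-scid replicate 3, and D17H6S56E-5 in lacrimal gland without each of 3, reaching 0.0618 without NOD-scid replicate 2, and it reached 0.0935 with the RNA quality covariate. Its other lacrimal probe set did not pass (-0.13). Leaving out each library gave 15 to 23 shared probe sets, and 11 of the 18 genes had other probe sets, of which 50 of 92 values lay in the shared direction. In pairs of comparisons, 126 probe sets were called at both ages of the submandibular gland, 126 in the same direction, against 0.354 higher and 0.744 lower for independent lists. Pancreas and lacrimal gland shared 43 calls, 41 in the same direction, against 0.281 higher and 0.720 lower. Of 679 probe sets called at least once, 521 were called in 1 comparison, 158 in at least 2 and 7 in opposite directions. Over all probe sets, which are not independent replicates, the log2 differences of 2 comparisons correlated between 0.0976 and 0.271.

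**Figure D2:**
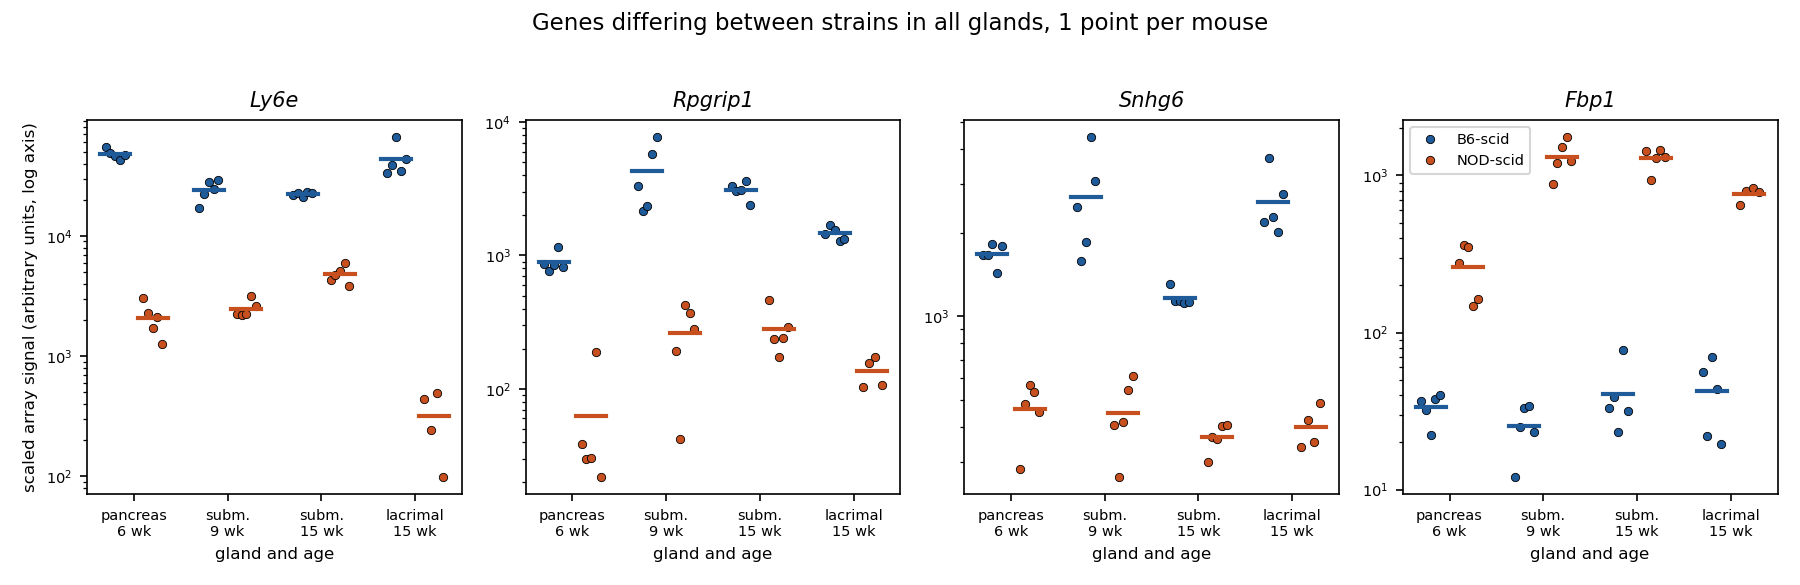
Scaled signal (log axis, arbitrary units) of Ly6e, Rpgrip1, Snhg6 and Fbp1 in pancreas, submandibular gland (subm.) at 9 and 15 weeks and lacrimal gland, with 1 point per mouse, B6-scid in blue and NOD-scid in orange, and a line at the arithmetic mean of each group. Ly6e, Rpgrip1 and Snhg6 lie lower and Fbp1 higher in NOD-scid in all 4, Fbp1 with log2 differences of 2.08 to 4.52.

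With age, transcripts of the pancreatic enzymes Prss2 and Cela1 and of an odorant-binding protein fell in the submandibular gland of B6-scid mice, and Gpt2 rose. Trypsin Prss2 fell by 4.34 (SE 0.78, adjusted p = 0.0102) from 1779 ± 807 at 9 weeks to 54.3 ± 38.98 at 15 weeks (n = 5 each). Elastase Cela1 fell by 3.40 (SE 0.67) from 1693 ± 845 to 104 ± 10.8, and Reg2 fell by 3.51 (SE 0.67). Pdk4, an inhibitor of pyruvate dehydrogenase that rises in fasting, fell by 3.38 (SE 0.57) from 5534 ± 2818 to 505 ± 309. The peptidase Mme rose by 2.27 (SE 0.27, adjusted p = 0.00144) from 24.2 ± 9.09 to 240 ± 47.7, with 0 of its 4 other probe sets called but all 4 of the same sign. The transaminase Gpt2 rose by 2.58 (SE 0.36) from 649 ± 329 to 3691 ± 1011. Obp1a fell by 4.62 (SE 1.00, adjusted p = 0.0260) from 16876 ± 6835 to 2882 ± 5735, with 13136 in replicate 1 of 15 weeks and 141 to 574 in the other 4. It was a call lost without each of 5 libraries, up to 0.0827 without B6-scid replicate 4 of 15 weeks (4.9e-04 to 0.0827 over its alternatives), and its other probe set was called lower too (-2.16). In B6-scid lacrimal gland Obp1a read 105570 ± 55315. In all, 393 probe sets were called, 250 higher and 143 lower at 15 weeks, 297 of them at least 2-fold. The count was 252 without B6-scid replicate 3 of 9 weeks, and 203, 122, 135 and 241 without B6-scid replicates 2, 3, 4 and 5 of 15 weeks.

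Acinar digestive enzymes lay lower at 15 weeks in B6-scid submandibular gland (20 tested, adjusted p = 7.6e-12), with 4 called and 14 adjusted over the list alone. The enzymes had an adjusted p = 0.233 with an estimated correlation (1.6e-17 to 0.233 over their alternatives). Of 30 genes for ER stress and protein folding (adjusted p = 3.8e-06), 3 were called higher, 8 adjusted over the list alone. These were Sel1l (1.09, SE 0.22, 2832 ± 471 against 1317 ± 235) and Herpud1 (0.91, SE 0.19), both of ER-associated degradation, and Dnajc3 (1.16). The other probe set of Sel1l (0.23) and the 5 others of Dnajc3 (-0.70 to 1.65) did not pass. That list had an adjusted p = 0.229 with an estimated correlation (5.3e-08 to 0.229 over its alternatives). The 3 calls ended without each of 2, 3 and 11 libraries, reaching 0.0655 and 0.0710 without B6-scid replicate 3 of 15 weeks for Sel1l and Herpud1 and 0.120 without replicate 4 for Dnajc3. All 3 also ended with the RNA quality covariate, at 0.0542, 0.0566 and 0.0517, with log2 changes of 0.95, 0.80 and 1.24. Of 33 ribosomal protein genes (adjusted p = 6.4e-06), 3 were called lower, Rps10 (-1.04, SE 0.21, 10943 ± 2698 against 22324 ± 4492), Rps28 (-0.92) and Rpl41 (-1.02), and Rps29 was called higher (0.93). The 2 other Rps28 probe sets did not pass and lay on opposite sides (-0.71 and 0.96). After quantile normalization Rps28 lay at -0.32 (adjusted p = 0.368), Rpl41 at -0.37 (adjusted p = 0.325) and Rps29 at 0.89 (adjusted p = 0.0602). Adjusted over the list alone there were 13 lower and 1 higher. That list had an adjusted p = 0.233 with an estimated correlation and 0.0747 after quantile normalization (6.0e-07 to 0.233 over its alternatives). Its 4 calls each ended without B6-scid replicate 3 of 15 weeks, up to 0.114 for Rps29. Oxidative phosphorylation (52 tested, adjusted p = 0.00346) had 1 gene called lower, 2 adjusted over the list alone. This list had an adjusted p = 0.488 with an estimated correlation (1.1e-04 to 0.488 over its alternatives), 0.124 with the RNA quality covariate and 0.204 without the 9-week samples numbered 4 and 5.

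Secretory transcripts of B6-scid submandibular gland lay lower at 15 weeks, but both lists lost their call after quantile normalization, with the RNA quality covariate and without the 9-week samples numbered 4 and 5. With the covariate the adjusted p was 0.204 for salivary and 0.165 for lacrimal secretory genes, and without those samples 0.196 for both. The median of the lacrimal list was -0.36 with the covariate and -0.32 without it, and that of the salivary list -0.09 and -0.24. Of 21 salivary secretory genes (adjusted p = 0.0320), 3 were called lower, for example Mucl2 (-1.04) and Car6 (-1.01), 6 lower and 1 higher adjusted over the list alone. After quantile normalization Mucl2 lay at -0.12 (adjusted p = 0.700) and Car6 at -0.19 (adjusted p = 0.629), and Car6 lost its call without each of 8 libraries. The salivary genes had an adjusted p of 0.233 with an estimated correlation and 0.728 after quantile normalization (0.00692 to 0.728 over their alternatives). Single libraries mattered too, with 0.0609 and 0.0613 without B6-scid replicates 2 and 5 of 15 weeks and 0.0890 without B6-scid replicate 5 of 9 weeks. Of 20 lacrimal secretory genes (adjusted p = 0.00916), 5 were called lower, 7 lower and 2 higher adjusted over the list alone. The list had an adjusted p of 0.269 with an estimated correlation and 0.521 after quantile normalization (3.4e-04 to 0.521 over its alternatives), and 0.0691 without B6-scid replicate 5 of 9 weeks. Pip, a secreted protein of salivary and lacrimal glands, fell by 1.01 (SE 0.18, adjusted p = 0.00894) from 96517 ± 19977 to 47696 ± 8042, and by 0.34 (adjusted p = 0.203) after quantile normalization (0.00193 to 0.203 over its alternatives). Klk1 was lower by -0.88 (adjusted p = 0.0400) but higher by 0.07 after quantile normalization (adjusted p = 0.844, 0.0138 to 0.844 over its alternatives). It lost its call without each of 11 libraries, up to 0.121 without B6-scid replicate 3 of 15 weeks.

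In NOD-scid submandibular gland, Obp1a fell by 7.31 between 9 and 15 weeks (SE 1.00, adjusted p = 0.00281) from 15705 ± 11496 to 44.7 ± 70.3 (n = 5 each), while its other probe set did not pass (-1.71, adjusted p = 0.0922). Cpa1, a carboxypeptidase, fell by 3.70 (SE 0.69) from 3473 ± 5713 to 100 ± 77.0, Cela1 fell by 3.57 (SE 0.67) and Reg2 fell by 3.61 (SE 0.67) from 2224 ± 3531 to 58.1 ± 44.0. NOD-scid replicate 1 raised the 9-week means, with Cpa1 at 13672 against 515 to 1483 in the other 4 and Reg2 at 8499 against 350 to 1343. Cpa1 lost its call with adjustment within each design (0.0701). The ribonuclease Rnase1 fell by 2.52 (SE 0.39) and Gm14743 fell by 3.44 (SE 0.62) from 3203 ± 1913 to 211 ± 59.3, a call lost without the 9-week samples numbered 4 and 5 (-2.81, adjusted p = 0.0709). The calcium sensor Stim2 rose by 2.20 (SE 0.41, adjusted p = 0.0149) and Cyp2d22 by 2.04 (SE 0.40, adjusted p = 0.0176). Cyp2d22 reached 0.0533 without NOD-scid replicate 1 of 15 weeks. In all, 314 probe sets were called, 183 higher and 131 lower, 269 of them at least 2-fold. The split was 245 higher and 110 lower under median scaling and 175 and 81 after quantile normalization. The count was 200 and 191 without NOD-scid replicates 4 and 5 of 9 weeks, 183 and 189 without B6-scid replicates 2 and 3 of 15 weeks, which share the fit, and 111, 116, 119, 147 and 199 without NOD-scid replicates 1, 2, 3, 4 and 5 of 15 weeks.

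Of 20 acinar digestive enzymes in NOD-scid submandibular gland (adjusted p = 9.1e-16), 7 fell, 13 adjusted over the list alone. Of 6 Reg genes (adjusted p = 0.00962) 1 fell, Reg2, 4 adjusted over the list alone. These lists had an adjusted p = 0.215 and 0.444 with an estimated correlation (2.4e-18 to 0.215 and 0.00174 to 0.444 over their alternatives). The Reg list reached 0.0841 without NOD-scid replicate 1 of 9 weeks. Of 20 lacrimal secretory genes (adjusted p = 2.4e-04), 5 were called lower, 8 lower and 1 higher adjusted over the list alone. Their test had an adjusted p = 0.215 with an estimated correlation and 0.345 after quantile normalization (5.7e-05 to 0.345 over their alternatives). The ABP-family gene Scgb1b27 fell by 1.20 from 165810 ± 29394 to 71434 ± 3184, and by 0.40 (adjusted p = 0.143) after quantile normalization (0.00162 to 0.287 over its alternatives). Of 33 ribosomal protein genes (adjusted p = 5.4e-06), 1 fell, Rps10 (-1.18, SE 0.21, 11631 ± 2086 against 26731 ± 6724), 10 adjusted over the list alone. The ribosomal list had an adjusted p = 0.215 with an estimated correlation (7.1e-08 to 0.215 over its alternatives). The ER folding genes lay higher (30 tested, adjusted p = 0.00962), with 0 called, 5 adjusted over the list alone, and Sdf2l1 at 1.34 (adjusted p = 0.0543). The folding list had an adjusted p of 0.406 with an estimated correlation (0.00156 to 0.406 over its alternatives) and 0.0530 without NOD-scid replicate 4 of 9 weeks. Salivary secretory genes (21 tested, adjusted p = 0.0780) had 4 called lower, 5 adjusted over the list alone. For the kallikreins, the median of 0.10 differed in sign from the mean of -0.03 and the downward camera test (adjusted p = 0.597).

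**Figure D3:**
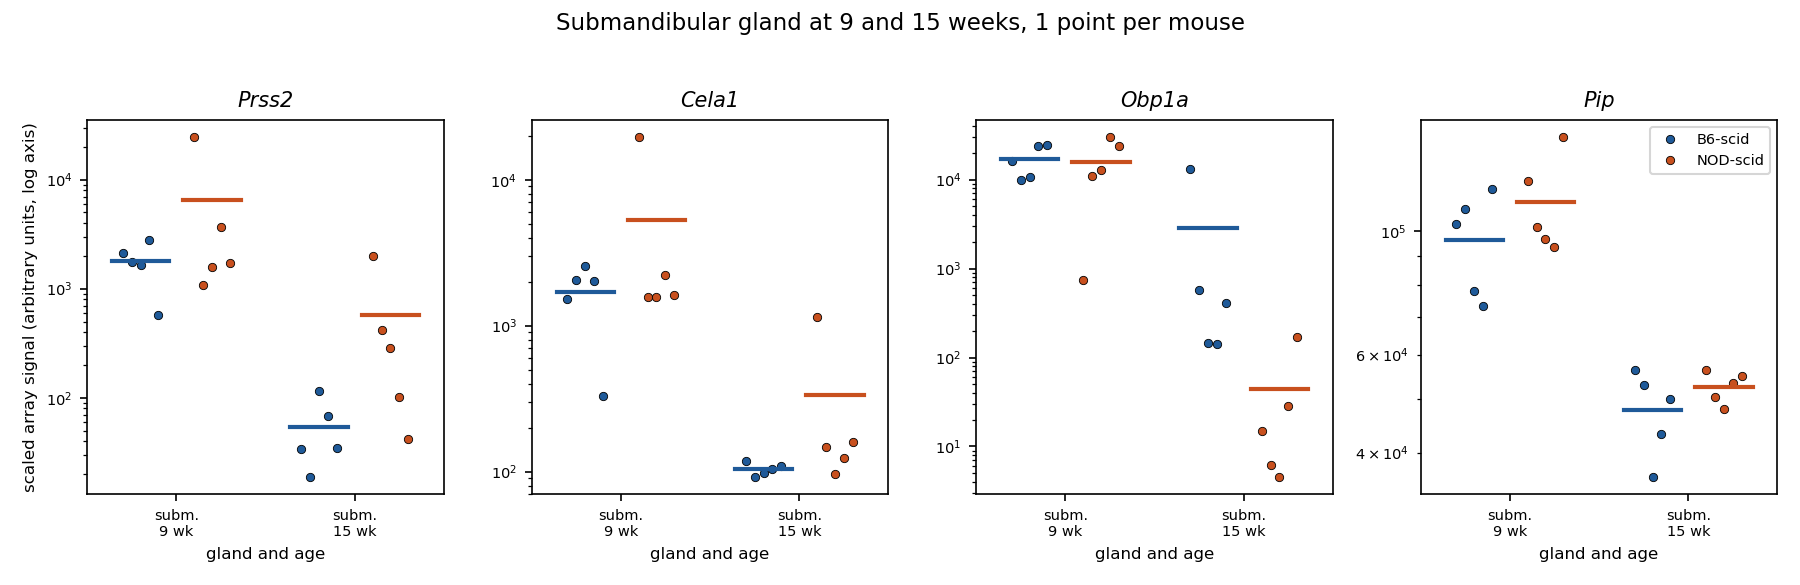
Scaled signal (log axis, arbitrary units) of Prss2, Cela1, Obp1a and Pip in submandibular gland (subm.) at 9 and 15 weeks, with 1 point per mouse, B6-scid in blue and NOD-scid in orange, and a line at the arithmetic mean of each group. Obp1a fell from a mean of 15705 to 44.7 in NOD-scid and from 16876 to 2882 in B6-scid, where 1 mouse read 13136 at 15 weeks and the other 4 read 141 to 574, and the fall of Pip did not pass after quantile normalization.

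The strain difference of the submandibular gland was also tested for a change between 9 and 15 weeks. With limma 0 probe sets were called at an adjusted p under 0.05, while 1605 had an unadjusted p under 0.05, and each alternative of scaling, filter, pseudocount and fit also gave 0. Leaving out NOD-scid replicate 2 of 9 weeks or NOD-scid replicate 3 of 15 weeks gave 1. Obp1a fell in both strains, and the 0 calls do not show that the falls were equal. Of 30 lists, 0 were called, with a lowest adjusted p of 0.347, and 1 without B6-scid replicate 1 of 15 weeks or with the probe set of highest mean over all designs. Bpifa2 (0.96, SE 0.99) and Prkdc (0.55), the gene mutated in both strains, did not pass, both at an adjusted p of 0.999.

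At 15 weeks, the strain difference was compared between lacrimal and submandibular gland, to ask which strain differences depend on the gland. H2-D1, a class I heavy chain, differed on all 3 of its probe sets. On the probe set with the smallest p it differed by -2.52 (SE 0.33, adjusted p = 6.6e-04), since NOD-scid mice had 2111 ± 380 (n = 4) against 8738 ± 4171 (n = 5) in lacrimal gland and 19615 ± 1697 against 13196 ± 1805 (n = 5 each) in submandibular gland. B2m differed in the same way, by -2.82 (SE 0.41, adjusted p = 0.00239), with 14106 ± 2934 against 9449 ± 2808 in submandibular gland. Agr2, which folds mucins, differed by 3.00 (SE 0.30, adjusted p = 4.7e-05), at 17398 ± 2193 against 8254 ± 747 in lacrimal gland and 86.2 ± 35.0 against 410 ± 97.5 in submandibular gland, while its other probe set did not pass (-0.08). Notch4 differed by 4.24 (SE 0.47), with submandibular levels of 366 ± 125 and 252 ± 56.7, while its 2 other probe sets lay on the opposite side without passing (-0.21 and -0.27). St6galnac1 differed by -4.37 (SE 0.57), since its lacrimal levels were 76.0 ± 27.1 and 108 ± 131, and Ly6e, lower in NOD-scid in both glands, by -4.87 (SE 0.42), with 0 of its 2 other probe sets called. Fads2b differed by -2.90 (SE 0.48), at 22884 ± 6354 against 7089 ± 1327 in submandibular gland and 1257 ± 120 against 3467 ± 2182 in lacrimal gland. In all, 103 of 31441 probe sets were called, 48 higher and 55 lower, 101 of them at least 2-fold. Leaving out each library gave 69 to 115 calls.

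Class I presentation had the 1 list difference between glands that held with an estimated correlation (18 tested, adjusted p = 5.6e-05, and adjusted p = 0.00571 with an estimated correlation, 7.5e-06 to 0.00571 over its alternatives). In it 2 genes were called lower, H2-D1 and B2m, and 7 adjusted over the list alone, and H2-K1 was called lower on 1 of its 2 other probe sets (-1.97, adjusted p = 0.00617) and not on the other (-0.04, adjusted p = 0.990). The ER folding genes differed upward (31 tested, adjusted p = 2.7e-09), with 2 called, Sdf2l1 (1.62, SE 0.31, adjusted p = 0.0225) and Creld2 (1.54, SE 0.32, adjusted p = 0.0461). There were 11 adjusted over the list alone, and the list had an adjusted p = 0.0722 with an estimated correlation (3.8e-12 to 0.0722 over its alternatives). In submandibular gland Sdf2l1 read 1046 ± 274 in NOD-scid and 1142 ± 186 in B6-scid. Sdf2l1 lost its call without each of 2 libraries, up to 0.0545 without NOD-scid lacrimal replicate 1, and Creld2 without each of 15, up to 0.105 without NOD-scid lacrimal replicate 3. Over all alternatives they ran from 0.00144 to 0.0740 and from 0.00259 to 0.140, the highest without both B6-scid samples high in salivary transcripts for Sdf2l1 and with the RNA quality covariate for Creld2. Kallikreins and growth factors differed downward (14 tested, adjusted p = 4.4e-07), with 0 called and 8 adjusted over the list alone. They had an adjusted p = 0.122 with an estimated correlation (2.6e-14 to 0.122 over their alternatives). Acinar enzymes (15 tested, adjusted p = 0.00598) had 0 called and 2 lower adjusted over the list alone, and extracellular matrix (38 tested, adjusted p = 0.00417) 0 and 0. These lists had an adjusted p = 0.262 and 0.106 with an estimated correlation (0.00156 to 0.262 and 6.2e-04 to 0.106 over their alternatives).

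The other lists that differed between the glands did not hold with an estimated correlation. Macrophage genes (22 tested, adjusted p = 0.0205) had 0 called and 3 lower adjusted over the list alone, with an adjusted p = 0.165 with an estimated correlation (6.2e-04 to 0.165 over their alternatives). Idd candidate genes (21 tested, adjusted p = 0.0205) had 2 called lower, 5 adjusted over the list alone. They had an adjusted p = 0.117 with an estimated correlation (0.00547 to 0.117 over their alternatives), and 0.106 without NOD-scid lacrimal replicate 4. Duct epithelium (15 tested, adjusted p = 0.0221) had 0 called and 0 adjusted over the list alone. The duct list had an adjusted p = 0.165 with an estimated correlation (0.00871 to 0.285 over its alternatives, the highest without both B6-scid samples high in salivary transcripts, where its median went from -0.44 to -0.13). It had 0.0780 without B6-scid lacrimal replicate 2 and 0.0520 without NOD-scid lacrimal replicate 3. Interferon response genes (32 tested, adjusted p = 0.0221) had 0 called and 1 lower adjusted over the list alone. Their test had an adjusted p = 0.510 with an estimated correlation (1.8e-04 to 0.510 over their alternatives). They reached 0.114 and 0.0716 without B6-scid lacrimal replicates 4 and 5, and 0.0600 and 0.0595 without NOD-scid lacrimal replicates 3 and 4. Salivary secretory genes (21 tested, adjusted p = 0.0221) had 1 called higher though the list tested lower, 1 higher and 2 lower adjusted over the list alone. The salivary list had an adjusted p = 0.510 with an estimated correlation (0.00209 to 0.858 over its alternatives). Without both B6-scid lacrimal replicates 2 and 3 its median went from -0.96 to -0.08 and its adjusted p to 0.858. It reached 0.141 and 0.122 without each of these in turn, 0.0547 and 0.0600 without NOD-scid lacrimal replicates 1 and 3, and 0.0510 without NOD-scid submandibular replicate 2. Oxidative phosphorylation genes differed upward (53 tested, adjusted p = 0.0221), with 1 called, 1 higher and 2 lower adjusted over the list alone. These genes had an adjusted p = 0.380 with an estimated correlation (0.00355 to 0.380 over their alternatives) and 0.177 with the RNA quality covariate. They reached 0.0533 and 0.0569 without B6-scid lacrimal replicates 1 and 5, and 0.122 and 0.0664 without replicate 5 of the B6-scid and of the NOD-scid submandibular samples.

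**Figure D4:**
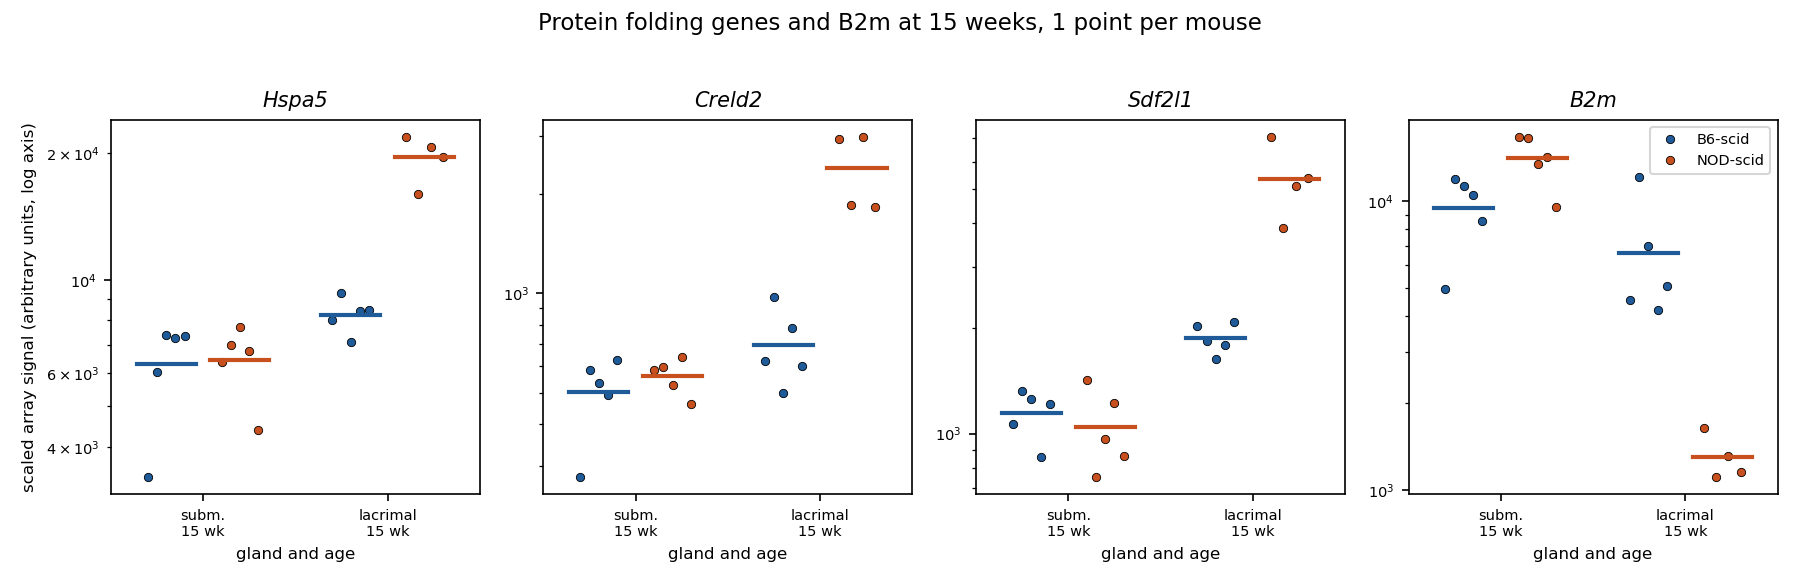
Scaled signal (log axis, arbitrary units) of Hspa5, Creld2, Sdf2l1 and B2m in submandibular (subm.) and lacrimal gland at 15 weeks, with 1 point per mouse, B6-scid in blue and NOD-scid in orange, and a line at the arithmetic mean of each group. In lacrimal gland the mean of Hspa5 is 19566 in NOD-scid and 8263 in B6-scid and that of B2m 1303 and 6602, while in submandibular gland B2m lies at 14106 and 9449.

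Several lists were not called in any comparison. Markers of T cells reached a lowest adjusted p of 0.459 and those of B cells and immunoglobulin 0.467, both in pancreas, and NK cell genes 0.287 (age in B6-scid). Dendritic cell genes reached 0.566 and lymph node stroma 0.723, both in the comparison between glands, neutrophil genes 0.118, chemokines and cytokines 0.269 and proliferation genes 0.305, all in submandibular gland at 15 weeks. Islet genes reached 0.0709 in the comparison between glands, Harderian and sebaceous genes 0.0950, complement genes 0.558 and skeletal muscle genes 0.269, all with age in B6-scid. Oxidative stress genes reached 0.180 and endothelium 0.297 in lacrimal gland, apoptosis genes 0.403 in submandibular gland at 9 weeks, and sublingual genes 0.743 in pancreas, where 5 were tested. Aqp5, the water channel of salivary and lacrimal acini, did not pass in any strain comparison, with log2 differences of -0.21 in pancreas, 0.16 and 0.02 in submandibular gland at 9 and 15 weeks and 0.18 in lacrimal gland. Hc, which encodes complement C5, did not pass in pancreas (0.91, adjusted p = 0.488), and Nnt did not pass in pancreas (0.50, adjusted p = 0.491) or lacrimal gland (0.97, adjusted p = 0.240).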

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

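The tests of submandibular RNA, of a strain difference, of pancreatic RNA, of digestive enzymes alone and of lacrimal RNA were chosen only after the results were seen, while those of parotid-type RNA (Dnase1), of other probe sets and of other splits of the samples were fixed before their results were seen. All were run on the data in which the patterns were noticed.

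Salivary secretory transcripts stood far apart in B6-scid lacrimal replicates 2 and 3, in Amy1, Bpifa2, Prpmp5 and Smr3a, chosen after their values were seen, with Prpmp5 at 76679 and 82367 against 110 to 221 in the other 3 B6-scid mice. Submandibular RNA alone was excluded as the source, since the lower of both samples exceeded the highest submandibular sample by a median log2 of 6.66 over these 4 transcripts (3.00 to 7.26). A strain difference was excluded as the whole cause, since 2 of 5 B6-scid samples, not 5, lay above every NOD-scid sample in all 4 transcripts. For Bpifa2 alone all 5 did (at least 348 against at most 75.8), so a strain difference stays open as part of its account. RNA of parotid-type salivary tissue in both samples is a candidate source: Dnase1, abundant in mouse parotid gland, was 129410 and 132480 there against at most 98167 in the other lacrimal samples, a ratio of 1.32 for the lower of both. Lacrimal expression in these 2 mice themselves was not tested and stays open.

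The digestive enzyme list lay higher in submandibular gland at 9 than at 15 weeks in both strains and the Reg list in NOD-scid, though none held with an estimated correlation (0.215 to 0.444). Of 6 Reg genes 1 was called in each strain. Cela1 was highest in NOD-scid replicate 1 of 9 weeks (19646), and Obp1a was higher at 9 weeks too. Pancreatic RNA at 9 weeks stays open. Of 29 probe sets abundant in pancreas and low in lacrimal gland, 26 were higher at 9 weeks (89.7%, under the 90% set). So were 10 of the 12 outside both lists (83.3%), but unnamed ones (log2 up to 5.05, named up to 1.09) may be enzymes. An age change of enzymes alone also stays open. The 12 lay at a median log2 of -0.47 (SD 2.01) against the level that the share set by the listed genes (0.396%) implies, with a spread too wide to decide. Pancreatic RNA was excluded for Obp1a, whose pancreas mean was 8.6e-04 of its 9-week submandibular mean. Lacrimal RNA stays open as a source of Obp1a. With the 7 lacrimal samples other than B6-scid replicates 2 and 3 as source, 11 of 13 lacrimal-abundant probe sets were higher at 9 weeks, which decided nothing. Only 4 could be set against the level that the share set by Obp1a (20.2%) implies, at a median log2 of -2.59 (SD 1.64). They were Dnase1 at 491 against 14775, Gm12888 at 1138.5 against 13772, Gm14743 at 4126 against 12422 and an unnamed one at 4722 against 13738. With all 9 as source the median was -3.63 over 6 probe sets (SD 1.43), but 1 of these, Smr3a, was abundant only in replicates 2 and 3, so this excludes nothing. Age itself, which the design names, stays open, untested apart from dissection.

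Of the 22 strain differences shared by all 4 comparisons, many were large and seen on 1 probe set of the gene. Strain sequence variants under single probe sets may account for part of them: other probe sets of the same genes lay in the shared direction in 50 of 92 values (54.3%) and in 4 of the 7 genes that were not tied (exact binomial p = 1, two-sided). Of those other values, 8 were called in the shared direction, all of Ly6e, Ctsc or Apobec3. For these genes a variant under a single probe set was not the whole account. The other AI506816 probe set was called in the opposite direction in submandibular gland at both ages and in lacrimal gland. A difference in expression between the strains, which the design names, stays open. Of 100 splits of the samples, only the real one shared any probe sets (22). The others removed the strain differences, so they cannot test sharing.

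The strain difference itself differed between lacrimal and submandibular gland for 103 probe sets by the interaction test. The named genes were Ly6e (-4.87), St6galnac1 (-4.37), Fads2b (-2.90), E330020D12Rik (-2.84), B2m (-2.82) and H2-D1 (-2.52) on the lower side, and Notch4 (4.24), BC018473 (3.83), Agr2 (3.00), Psmd10 (2.99), Egfl6 (2.84), Sdf2l1 (1.62), Creld2 (1.54) and Atp5j (0.98) on the higher side. The other probe sets of Notch4, Ly6e, Agr2, Psmd10 and E330020D12Rik did not pass. Atp5j lost its call without each of 18 of the 19 libraries, up to 0.109 without NOD-scid lacrimal replicate 3, Creld2 without each of 15, up to 0.105 without the same one, and Sdf2l1 without each of 2, up to 0.0545 without NOD-scid lacrimal replicate 1.

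Among 611 pairs of a named gene and a group of 4 or 5 samples, 40 held 1 sample far from the others, where chance gives about 1 in 20 groups. The number given for each is the gap to the nearest sample over the whole range. Salivary and pancreatic transcripts made up several of them. In NOD-scid lacrimal replicate 4, Klk1 (0.913, 3983 against 252 to 325), Prol1 (0.884, 76723 against 1259 to 2043) and Psmb8 (0.874) stood apart. In NOD-scid submandibular replicate 1 of 9 weeks, Cela1 (0.861) and Reg3a (0.766, 2190 against 196 to 356) lay above the others and Obp1a below (0.725, 745 against 11008 to 30157). Cela1 also stood apart in NOD-scid replicate 1 of 15 weeks (0.818) and B6-scid replicate 5 of 9 weeks (0.743), and Obp1a in B6-scid replicate 1 of 15 weeks (0.711, 13136 against 141 to 574).

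In pancreas the outlying samples were B6-scid replicate 4 for Hsd17b13 (0.7103, 5584 against 7091 to 7817), replicate 5 for Timmdc1 (0.809) and replicate 1 for Bpifa2 (0.840), and NOD-scid replicate 1 for Wdr92 (0.742) and Sesn2 (0.860), replicate 3 for Smc5 (0.765) and replicate 4 for Greb1 (0.713). In submandibular gland at 9 weeks they were B6-scid replicate 3 for Eny2 (0.734), NOD-scid replicate 5 for Zgrf1 (0.711) and NOD-scid replicate 2 for Ndufb5 (0.851) and Nsun3 (0.796). At 15 weeks, B6-scid replicate 1 stood apart for Abhd1 (0.718), H2-Bl (0.774) and Hc (0.896), replicate 3 for BC018473 (0.789), H2-Eb1 (0.806), Prp2 (0.787) and Isg20 (0.792), and replicate 4 for Rnase1 (0.747). NOD-scid replicate 2 of 15 weeks stood apart for Fbp1 (0.744), Cidea (0.728) and Gbp3 (0.717), replicate 3 for Pigv (0.732), and replicate 5 for Arg1 (0.833), Klk1b8 (0.859) and Pdia6 (0.820). In lacrimal gland they were B6-scid replicate 2 for Noct (0.716), Aqp5 (0.807) and Atp5j (0.840), and NOD-scid replicates 2 for Irf9 (0.899) and 3 for Lgals3 (0.917). The most for any sample were 4, in B6-scid submandibular replicates 1 and 3 of 15 weeks.

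For each comparison, 100 splits of its samples into groups of the same sizes were counted, the real one included. In 7 of the 8 comparisons, 1 of 100 gave as many called probe sets. For the strain and age comparisons this excludes chance for those counts. Between glands it cannot, because the splits mixed the strains within each gland and so removed the strain differences themselves. The real counts and the highest of the other splits were 186 and 6 in pancreas, 359 and 69 in submandibular gland at 9 weeks, 191 and 2 at 15 weeks, 330 and 11 in lacrimal gland, 393 and 21 for age in B6-scid, 314 and 4 for age in NOD-scid, and 103 and 56 between glands. For strain by age, 100 of 100 splits gave as many as the real 0, with 2 at most, and 100 of 100 gave as many lists as the real 0, with 7 at most. For the number of lists, 1 of 100 splits gave as many in pancreas (real 6, highest other 4) and between glands (real 11, highest other 9), where the same limit holds. Chance was not excluded for the number of lists in submandibular gland at 9 weeks (34 of 100, real 3, highest other 7) and at 15 weeks (9 of 100, real 6, highest other 10), in lacrimal gland (5 of 100, real 6, highest other 7), or for age in B6-scid (5 of 100, real 6, highest other 7) and NOD-scid (6 of 100, real 5, highest other 7).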

How the results depend on the processing

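Leaving out the 9-week samples numbered 4 and 5, leaving out B6-scid lacrimal replicates 2 and 3 and using the replicate number within age were chosen after seeing the data. The cause was not tested for any moved or reversed value below, except that fewer samples or genes enter some fits. No called list changed the direction of its test, though the median of the Idd candidate genes in lacrimal gland went from -0.37 to 0.01 with no filter on low values, and no setting moved the median of all genes by more than 0.061. The deposited scale changed nothing, since the arrays had been scaled alike before deposit.

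With an estimated correlation, the number of called lists was 0 in pancreas, 0 and 3 in submandibular gland at 9 and 15 weeks, 0 in lacrimal gland, 0 for age in B6-scid, 0 for age in NOD-scid and 1 between glands. Quantile normalization left 0 lists in pancreas. With the probe set of highest mean, 5 lists were called in submandibular gland at 9 weeks and 1 for strain by age, and without the 9-week samples numbered 4 and 5, 3 for age in B6-scid.

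In 1 fit of all 39 samples the called probe sets numbered 348 in pancreas, 773 in lacrimal gland, 1033 for age in B6-scid and 722 for age in NOD-scid. eBayes with trend and robust settings gave 345 in pancreas, 648 in lacrimal gland, 707 for age in B6-scid and 179 between glands. The RNA quality covariate gave 118 in pancreas and 110 in lacrimal gland. The larger pseudocount gave 594 for age in B6-scid, where leaving out the 9-week samples numbered 4 and 5 gave 632. Without B6-scid lacrimal replicates 2 and 3, 145 were called in lacrimal gland.

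The replicate number as a block gave 60 called probe sets in pancreas and 35 in lacrimal gland, against 302 and 174 in submandibular gland at 9 and 15 weeks, 335 and 242 for age in B6-scid and NOD-scid, 0 for strain by age and 82 between glands (113 with the mouse as a random block). Under the block the adjusted p of named genes reached 0.185 for Creld2, 0.208 for Manf and 0.0550 for Rps28 in pancreas, and 0.0561 for Ifih1 at 15 weeks (0.141 with the block within age). Cxcl1 at 9 weeks reached 0.0598 with the block within age. In lacrimal gland it reached 0.139 for Hspa5, 0.174 for Creld2, 0.130 for Sdf2l1, 0.162 for Pdia4, 0.116 for B2m, 0.0683 for Cxcl1, 0.1004 for Tyrobp and 0.107 for Ifi204. Between glands it reached 0.117 for Creld2 and 0.0539 for Sdf2l1. Same-numbered samples of 2 groups had deviations that correlated weakly, between -0.0689 and 0.0908. At most 3 samples of a group correlated best with their own number, in submandibular gland at 9 weeks and in lacrimal gland between strains. Same-number correlations were 0.0205 to 0.0908 in the first (others -0.0969 to 0.0879). They were -0.00356 to 0.0488 in the second (others -0.0402 to 0.0107). A factor shared by same-numbered samples was not excluded there.

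Leaving out each library gave 112 to 161 calls in pancreas (lowest without B6-scid replicate 3), 148 to 258 in lacrimal gland (lowest without NOD-scid replicate 3), 122 to 428 for age in B6-scid (lowest without B6-scid replicate 3 of 15 weeks), 111 to 350 for age in NOD-scid (lowest without NOD-scid replicate 1 of 15 weeks) and 0 to 1 for strain by age. The called lists numbered 2 to 6 in pancreas (2 without B6-scid replicate 3), 2 to 5 in submandibular gland at 9 weeks and 0 to 1 for strain by age. The count of shared strain differences was 15 to 23, and 16 to 27 under the other settings.

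Reversals concerned genes that were not called, except Klk1 with age. After quantile normalization Reg1 in pancreas was 0.031, Klk1 was -0.083 and -0.072 between strains in submandibular gland at 9 and 15 weeks, 0.068 and 0.079 with age in B6-scid and NOD-scid and 0.011 for strain by age, and Prol1 was 0.044 with age in B6-scid. With the RNA quality covariate Aqp5 was 0.10 in pancreas and -0.0019 in submandibular gland at 15 weeks, Bpifa2 0.52 with age in B6-scid, Prkdc 0.0019 with age in NOD-scid, Klk1 0.022 for strain by age, and Hc 0.27 and Nnt 0.044 between glands. Without the 9-week samples numbered 4 and 5 Klk1 was -0.0024 between strains at 9 weeks and 0.083 for strain by age, and Bpifa2 0.39 with age in B6-scid. Hc was 0.029 between glands at the larger pseudocount, and Nnt 0.058 there without B6-scid lacrimal replicates 2 and 3.

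Leaving out single libraries turned further genes that were not called. The ranges were -0.42 to 0.13 for Aqp5, strain difference, pancreas 6 weeks, -0.0023 to 0.26 for Klk1, strain difference, submandibular gland 9 weeks, -0.42 to 0.076 for Prkdc, strain difference, submandibular gland 9 weeks, -0.034 to 0.16 for Klk1, strain difference, submandibular gland 15 weeks, and -0.080 to 0.13 for Aqp5, strain difference, submandibular gland 15 weeks. They were -0.91 to 0.071 for Bpifa2, age difference, B6-scid submandibular gland, -0.32 to 0.075 for Prkdc, age difference, NOD-scid submandibular gland, -0.56 to 0.12 for Egf, strain by age, submandibular gland, -0.18 to 0.083 for Klk1, strain by age, submandibular gland, and -0.17 to 0.18 for Hc, strain by gland at 15 weeks.

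Of the called genes that the naming rule chose, not all of which the text names, 19 of 23 in pancreas, 21 of 25 and 22 of 25 in submandibular gland at 9 and 15 weeks, 20 of 27 in lacrimal gland, 9 of 25 and 12 of 17 for age in B6-scid and NOD-scid and 11 of 14 between glands kept their call without each library. Quantile normalization ended 11 calls for age in B6-scid and 5 in NOD-scid, and the RNA quality covariate ended 10 in lacrimal gland and 10 for age in B6-scid. In the lacrimal simulation 25.9% of log2 changes of 1 were recovered, and 12.1% in that of strain by age.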

Other observations

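The test of genes near Prkdc and its direction had been written down before the values were seen, while its bounds and the test over single chromosomes were chosen only after.

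Both strains carry the scid mutation of Prkdc, taken from the same donor strain, so that the chromosome around it may be shared and hold fewer strain differences. Of 164 genes within 10 Mb of Prkdc in assembly GRCm38.p6, 4 (2.44%) were called in at least 1 strain comparison, for Gspt1, Sdf2l1, Sst and Zdhhc8, against 465 of 14850 (3.13%) elsewhere. The odds ratio was 0.773 (Fisher's exact test, two-sided, p = 0.821), 0.815 within 5 Mb (p = 1) and 0.693 within 20 Mb (p = 0.482), so the hypothesis was neither borne out nor excluded. Over single chromosomes, 0 held more or fewer strain differences than the rest after adjustment, with a lowest adjusted p of 0.355 (Fisher's exact test).

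The strain difference of Prkdc transcripts did not pass in submandibular gland at 9 weeks (-0.17, limma adjusted p = 0.913) or 15 weeks (0.38, adjusted p = 0.999). Pnliprp1, a lipase of the pancreatic family, was abundant in lacrimal gland, at 46544 ± 8001 in NOD-scid (n = 4) and 15344 ± 6145 in B6-scid (n = 5), and its strain difference did not pass between glands (1.66, limma adjusted p = 0.348). The secreted inhibitor Wfdc12, whose other probe set did not pass (-0.80), was lower in NOD-scid lacrimal gland (-3.17, SE 0.63, adjusted p = 0.0447), at 2787 ± 1157 against 34165 ± 30107, and lost that call without each of 7 of the 9 libraries, up to 0.121 without NOD-scid replicate 3 (1.2e-06 to 0.178 over its alternatives, the highest with the RNA quality covariate).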
